A study of Homo sapiens with 14 samples.

How the data were processed

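RNA of PANC-1 cells was extracted with Trizol and sequenced as 151-nt read pairs on an Illumina NextSeq 500, per the labels, in 14 libraries of 7 groups with 2 replicates each. The deposited counts are raw reads per gene for each library, as whole numbers without normalization, for 28120 genes. The deposited RPKM values (reads scaled to gene length and library total, rounded to 2 decimals) were made by the authors for 25447 genes, all of them also in the table of counts. The authors' notes name TopHat2, edgeR and the GRCh38 build without versions or roles. The counting tool, the annotation release, the strand setting, the gene lengths and the read total behind RPKM are not given in the sources used here. For that reason genes that overlap another gene or share reads with near-identical copies carry an unknown share of misassigned reads. In 8163 lines of the table of counts an extra empty field followed the symbol and was skipped; library columns were matched to the labels by name.

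Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM library sizes, filterByExpr by group (15181 genes, holding at least 99.953% of each library's reads), and quasi-likelihood fits of all 14 libraries with 1 mean per group, which left 7 residual degrees of freedom. Contrasts were PA minus DMSO at 3, 12 and 24 h, their average, the 3 differences between these effects, and DMSO at 3, 12 and 24 h minus DMSO at 0 h. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all tests were two-sided. The SE of a log2 change was its size divided by the square root of the F statistic, and CPM are TMM-normalised. Depth per library ranged from 26403984 to 35213154 reads. Intervals and floors (3 counts) cover counting error only.

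The comparisons, the tests, the naming rule and 32 gene lists were chosen before the data were examined. The lists cover NRF2 targets, aryl hydrocarbon receptor targets, sterol synthesis, fatty acid synthesis, p53 targets, ATF4 stress, endoplasmic reticulum chaperones, heat shock, hypoxia, immediate early genes, NF-kB inflammation, interferon response, DNA replication, G2/M and mitosis, DNA repair, apoptosis regulators, TGF-beta and YAP targets, mesenchymal genes, epithelial genes, extracellular matrix, metallothioneins, iron homeostasis, autophagy and lysosome, clock genes, Wnt and Notch targets, ribosomal proteins, RNAs of the mitochondrial genome, replication histones, nuclear RNAs, and markers of fibroblasts, leukocytes and endothelium. Lists with at least 3 measured members were tested with camera on voom values in limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated one, and adjusted over the lists of each comparison. The test asks whether a list's members moved more than other genes. After the GC corrections described below, camera was run on log2 CPM less the trend, not on voom values, and with the preset correlation only.

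Named genes were, for each PA time, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 2 CPM, both PA libraries beyond both DMSO libraries and a symbol that is not a clone name. To these came up to 4 members with the smallest p of each called list, 6 genes each way for the average and 4 each way for every other contrast. CDKN1A, MKI67, HMOX1, CXCL8, CDKN2A and GAPDH were always named. A symbol shared by several tested genes (20 symbols) was never used to merge them.

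GC content and length came from each gene's longest basic transcript in GENCODE 29, for 15071 tested genes (99.3%). An earlier definition, the median over basic transcripts, misplaced some genes and was replaced after the first library slopes had been seen; both were computed for the GC slopes, the GC and length correction, the matched lists and the genomic spans, and these tests came out the same way under either. The GC slope of a library is that of log2 CPM, less the gene's mean over libraries, on GC content. For the correction, each library's trend on GC content, or on GC content and log2 length, was fitted with natural splines (5 degrees of freedom) and entered as an offset. Matched lists replaced each member by 1 of its nearest genes in GC content, log2 length and mean log2 CPM, 10000 times.

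Alternatives chosen beforehand were DESeq2 1.42.0 and its size factors within edgeR, no filter, at least 5 CPM in 2 libraries, a block for the replicate number, a minimum change of 2-fold, the 4 libraries of a comparison alone, limma on log2(RPKM + 1) and log2(RPKM + 0.1), an RPKM of at least 1 in 2 libraries, an estimated correlation for lists, and leaving out each library. The GC corrections, their pairing with the block and the removal of 33 mitochondrial genes were added after the data were seen. Replicate numbers did not pair the libraries: of 21 pairs of groups, 2 had a correlation of residuals over 0.1, and the range was -0.22 to 0.24. The block was therefore kept as an alternative.

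The methods were tested on data simulated from the gene means, library sizes and spread of all 14 libraries, with 200 genes changed in the PA 12 h libraries. The larger difference between the real PA 12 h replicates was not built in. With edgeR, 4.48% of 1.5-fold, 62.7% of 2-fold and 95.5% of 4-fold changes were recovered and 5 unchanged genes were called. With GC trends of the observed size added, 3643 unchanged genes were called, and 4 after correction for GC content and length. The added trends were linear in the same GC values that the correction fits, so this shows only that it removes such trends. Of 40 random lists 0 passed camera. The simulated genes varied independently, so this check could not show false calls that come from correlation between genes. Fibroblast and endothelial markers, with 2 measured members each, were not tested as lists.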

Results

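RNA from PANC-1 cells, an established human pancreatic cancer line, was sequenced after exposure to proanthocyanidins (PA, plant polyphenols) at 20 micrograms per ml or to the vehicle DMSO. The 14 libraries form 7 groups of 2: DMSO at 0, 3, 12 and 24 h, and PA at 3, 12 and 24 h. Reads counted in genes ranged from 26403984 to 35213154 per library. The DMSO libraries held 27000477 and 35213154 reads at 0 h and 33232841 and 34115000 at 3 h. At 12 h they held 26403984 and 31076409 reads, and 30013257 and 29506963 at 24 h. The PA libraries held 31017197 and 35065628 reads at 3 h, 30721243 and 27801440 at 12 h, and 34359848 and 34202995 at 24 h. A count of 0 allows up to 3 reads, which is 0.0852 to 0.114 CPM (counts scaled to library size) depending on the library and covers counting error only. Of 28120 genes, 15181 passed the expression filter, and the spread between replicates (biological coefficient of variation) was 15.1%. The series text speaks of a biological replicate. Nothing in the sources used here says that replicates were separate cultures, so the p-values measure only the spread between these libraries. The first principal component of log2 CPM held 57.1% of the variance and the second 10.2%. In what follows, log2 changes are given ± SE, CPM and shares ± SD, with n = 2 per group, and adjusted p-values come from edgeR.

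The comparison of PA with DMSO at 3 h asked what changed first. CENPE, the kinetochore motor that moves chromosomes to the spindle equator, fell by 4.18 ± 0.372 on the log2 scale, from 108 ± 18.4 to 5.90 ± 2.36 CPM, which is 18.2-fold lower (adjusted p = 0.000172). CENPE (ENSG00000138778.10) lies on the minus strand of chromosome 4 at 103105806 to 103198409 (GRCh38, GENCODE 29). ANKRD12, a nuclear ankyrin repeat protein, fell by 3.48 ± 0.304. AKAP9, which anchors kinases at the centrosome and Golgi, fell by 3.37 ± 0.37, and the golgin GOLGA4 by 3.10 ± 0.327. Also lower were CEP290 of the ciliary base (-2.99 ± 0.356), ANKRD26 (-2.83 ± 0.265), the cytokinesis kinesin KIF20B (-2.81 ± 0.433) and CCDC18 (-2.74 ± 0.379). Adjusted p-values of these 8 ran from 0.000172 for CENPE to 0.00431 for KIF20B, and by the naming rule both PA libraries lay below both DMSO libraries. Without PA 3 h replicate 2, AKAP9 stood at -3.96, GOLGA4 at -3.69 and KIF20B at -3.43. Without PA 3 h replicate 1, KIF20B (-2.38, adjusted p = 0.149) and CCDC18 (-2.4, adjusted p = 0.1) no longer passed.

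Fewer genes rose at 3 h, and by less. INSIG1, the endoplasmic reticulum protein that holds sterol regulators inactive, rose by 1.19 ± 0.179 (adjusted p = 0.00363), from 95.9 ± 25.9 to 219 ± 4.44 CPM. INSIG1 (ENSG00000186480.11) lies on chromosome 7 at 155297776 to 155310235. The epithelial transcription factor ELF3 rose by 1.31 ± 0.266 (adjusted p = 0.0253) and the ephrin ligand EFNA1 by 1.17 ± 0.226 (adjusted p = 0.0192). DDIT4, an inhibitor of mTORC1, rose by 0.88 ± 0.171, the urokinase gene PLAU by 0.87 ± 0.163 and the endosomal protein gene PLEKHF1 by 0.87 ± 0.179. FAM159B (1.52 ± 0.326, adjusted p = 0.0324) and the potassium channel gene TMEM38A (1.03 ± 0.234, adjusted p = 0.0416) completed the 8 largest rises. The cell cycle inhibitor CDKN1A rose by 0.79 ± 0.173 (adjusted p = 0.0344). Without DMSO 3 h replicate 1, and again without PA 3 h replicate 1, none of these 8 genes nor CDKN1A passed. For INSIG1 the values were 0.94 (adjusted p = 0.0515) and 1.22 (adjusted p = 0.0547). Leaving out DMSO 3 h replicate 2 ended 7 of those 9 calls, for example that of ELF3 (adjusted p = 0.136), and leaving out PA 3 h replicate 2 ended 5, for example that of FAM159B (adjusted p = 0.178). FAM159B stood at 2.28 without DMSO 3 h replicate 2. On the log2(RPKM + 1) scale FAM159B changed by 0.02 (adjusted p = 0.783). MKI67, a marker of cycling cells (-0.38 ± 0.154, adjusted p = 0.247), the heme oxygenase gene HMOX1 (0.81 ± 0.242, adjusted p = 0.127), CXCL8 (-0.04 ± 0.248, adjusted p = 0.946) and GAPDH (0.43 ± 0.154, adjusted p = 0.198) did not pass.

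Among the gene lists fixed before the data were examined, 6 of 30 tested were called at 3 h by camera, and 0 were called once the correlation between genes was estimated. The sterol synthesis list had 1 of 16 measured members higher over all genes tested and 10 higher when adjusted over the list alone (camera adjusted p = 1.42e-08; adjusted p = 0.251 with an estimated correlation). Its median was 0.59, with INSIG1 past the threshold and DHCR7 (0.77, adjusted p = 0.0532) short of it. After correction for GC content and transcript length 9 members were higher over all genes (camera adjusted p = 4.71e-14), as were 1 of the fatty acid list and 2 of the hypoxia list, and 4 of the DNA repair list were lower. In the fatty acid synthesis list 0 of 10 members passed over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.251 with an estimated correlation), with SCD at 0.80 ± 0.196 (adjusted p = 0.0607). The hypoxia list had 0 of 15 members past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.000445; adjusted p = 0.251 with an estimated correlation). In the ATF4 stress list 1 of 13 members, DDIT4, was higher, and 2 were when adjusted over the list alone (camera adjusted p = 0.0346; adjusted p = 0.464 with an estimated correlation). The autophagy and lysosome list was called at the same camera adjusted p of 0.0346 with 0 of 16 members past the threshold (adjusted p = 0.477 with an estimated correlation). Neither of these last lists was called after correction for GC content and transcript length (adjusted p = 0.0677 for ATF4 stress and 0.12 for autophagy). Not called at first but called higher after that correction were NRF2 targets (camera adjusted p = 0.0373), NF-kB genes and iron genes (each camera adjusted p = 0.0213). Called lower after it were TGF-beta and YAP targets (camera adjusted p = 0.0213) and nuclear RNAs (camera adjusted p = 0.0344). Nuclear RNAs were also called with DESeq2-type size factors alone (camera adjusted p = 0.0477). List calls after the correction, here and below, used corrected log2 CPM in place of voom values. They were not repeated with an estimated correlation, so a changed call can also reflect the change of input. The DNA repair list was called lower (camera adjusted p = 0.000445; adjusted p = 0.396 with an estimated correlation), with 1 of 18 members lower, the damage kinase gene ATM (-1.12 ± 0.237, adjusted p = 0.0303), and 4 adjusted over the list alone. ATM lost its call without any 1 of the 4 libraries, with adjusted p from 0.0595 without PA 3 h replicate 2 to 0.521 without PA 3 h replicate 1. The mitosis list was not called (camera adjusted p = 0.382): 2 of 18 members were lower, 4 adjusted over the list alone, its median was 0.05 and its mean -0.42.

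In total 261 genes passed at 3 h, 21 higher and 240 lower, of which 216 changed at least 2-fold (7 higher and 209 lower). The unadjusted p was under 0.05 for 2600 genes. DESeq2 called 582 genes, 27.7% of them higher, against 8.05% in edgeR. With the spread taken from the 4 libraries of this comparison alone, edgeR called 1182 genes (248 higher and 934 lower). The genes called lower had a median GC content of 40.01% and a median transcript length of 4618 nt, against 48.9% and 3084 nt over all tested genes. After correction of each library for GC content and transcript length, 565 genes passed (114 higher and 451 lower), and 247 of the 261 were among them in the same direction. Without 1 library the total fell to 72 (DMSO replicate 1), 104 (DMSO replicate 2), 29 (PA replicate 1) or 178 (PA replicate 2).

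At 12 h ALDOC, an aldolase of glycolysis (ENSG00000109107.12, chromosome 17, 28573115 to 28577264), rose by 4.93 ± 0.37 on the log2 scale, from 3.58 ± 1.33 to 109 ± 35.04 CPM (adjusted p = 1.87e-06). ACSS2, which makes acetyl-CoA from acetate, rose by 3.99 ± 0.248 (adjusted p = 1.15e-06), and MVD of the mevalonate pathway by 3.41 ± 0.219. The desaturase gene SCD (ENSG00000099194.5, chromosome 10, 100347124 to 100364834) rose by 3.41 ± 0.214, from 568 ± 144 to 6026 ± 698 CPM. PFKFB4, a regulator of glycolysis, rose by 3.30 ± 0.255, the tight junction gene TJP3 by 3.65 ± 0.481, FAM43B by 3.40 ± 0.333 and the synaptotagmin gene SYT12 by 3.37 ± 0.334. CENPE again fell most, by 5.70 ± 0.414 (adjusted p = 1.59e-06), from 110 ± 10.7 to 2.11 ± 0.75 CPM. FAM111B, a replication-linked protease gene (ENSG00000189057.9, chromosome 11, 59107185 to 59127410), fell by 4.53 ± 0.452. The largest falls further included KIF20B (-4.52 ± 0.473), the centromere guard SGOL2 (-4.43 ± 0.466), the spindle gene ASPM (-4.38 ± 0.54), BRCA2 of homologous recombination (-4.20 ± 0.597), ATAD5, which unloads PCNA (-4.20 ± 0.563), and the meiotic gene SYCP2 (-4.14 ± 0.304). Without PA 12 h replicate 2, BRCA2 stood at -6.14, FAM111B at -5.51, ASPM at -5.49 and SGOL2 at -5.35. Without PA 12 h replicate 1, BRCA2 stood at -3.4, ASPM at -3.76 and TJP3 at 2.99. TJP3 stood at 4.57 and 3.06 without DMSO 12 h replicate 1 and 2. CDKN1A was higher by 1.59 ± 0.178 (adjusted p = 3.22e-05). In DMSO, CDKN1A had fallen by 1.53 ± 0.178 since 0 h (adjusted p = 0.00119), so PA libraries stood near the level of 0 h. HMOX1 rose by 1.60 ± 0.249 (adjusted p = 0.000308) and GAPDH by 1.47 ± 0.157 (adjusted p = 2.23e-05). MKI67 fell by 1.45 ± 0.157 (adjusted p = 2.49e-05). CXCL8 did not pass (-0.23 ± 0.272, adjusted p = 0.505). Its change was 0.845 (adjusted p = 0.00408) after correction for GC content and transcript length and -0.858 (adjusted p = 0.00501) without PA 12 h replicate 2.

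By lists, 11 of 30 were called at 12 h and 0 with an estimated correlation. In the sterol synthesis list 15 of 16 members rose, also 15 adjusted over the list alone, with a median of 1.82 (camera adjusted p = 5.47e-12; adjusted p = 0.0998 with an estimated correlation): INSIG1 rose by 2.78 ± 0.189, FDPS by 2.68 ± 0.192 and LSS by 2.54 ± 0.175. The fatty acid synthesis list had 6 of 10 members higher and 8 adjusted over the list alone (camera adjusted p = 7.23e-05; adjusted p = 0.0998 with an estimated correlation), among them FADS2 (3.07 ± 0.186), FASN (2.66 ± 0.224) and ACLY (1.99 ± 0.142). Hypoxia genes rose in 14 of 15 cases, and in 15 adjusted over the list alone (camera adjusted p = 2.31e-08; adjusted p = 0.0805 with an estimated correlation), such as the stress gene NDRG1 (2.19 ± 0.144), the glucose carrier SLC2A1 (1.87 ± 0.145) and BNIP3 of mitophagy (1.501 ± 0.136). Of the NRF2 targets 7 of 15 rose and 2 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.167 with an estimated correlation), with the transketolase gene TKT at 1.42 ± 0.201. ATF4 stress genes rose in 5 of 13 cases and fell in 1, as they did adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.485 with an estimated correlation), led by DDIT4 (2.64 ± 0.18), TRIB3 (1.52 ± 0.221) and ATF3 (1.34 ± 0.211). That list was not called after correction for GC content and transcript length (adjusted p = 0.148), and its member CEBPB (0.74 ± 0.159, adjusted p = 0.00217) then stood at -0.147. In the autophagy and lysosome list 10 of 16 members rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.417 with an estimated correlation). The autophagy receptor SQSTM1 rose by 1.40 ± 0.166 and the protease CTSD by 1.55 ± 0.194, while MCOLN1 (1.08 ± 0.205) stood at 0.285 (adjusted p = 0.112) after the correction. Fatty acid genes were then higher in 10 of 10 cases. Not called at first but called after it, with the preset correlation only, were iron genes as higher (camera adjusted p = 0.000788) and TGF-beta and YAP targets as lower (camera adjusted p = 0.0123).

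The lists called lower at 12 h were DNA repair, mitosis and DNA replication. DNA repair members were lower in 17 of 18 cases, 17 also adjusted over the list alone (camera adjusted p = 9.45e-08; adjusted p = 0.183 with an estimated correlation), such as BRCA1 (-2.52 ± 0.318), XRCC2 (-3.20 ± 0.412) and EXO1 (-1.32 ± 0.18). Of the mitosis list 13 of 18 fell, 13 adjusted over the list alone (camera adjusted p = 2.53e-06; adjusted p = 0.0998 with an estimated correlation), among them CENPF (-3.89 ± 0.34) and the spindle motor KIF11 (-2.44 ± 0.32). Without PA 12 h replicate 2, KIF11 stood at -3.24, BRCA1 at -3.11 and XRCC2 at -3.93. DNA replication genes fell in 13 of 20 cases, 13 adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.168 with an estimated correlation), among them MCM10 (-1.60 ± 0.18), the polymerase gene POLA1 (-1.24 ± 0.194), the origin licensing gene CDC6 (-1.09 ± 0.149) and MCM4 (-0.74 ± 0.115), and in 20 of 20 after the correction. Ribosomal protein genes, which share reads with near-identical pseudogenes, were higher in 17 of 20 cases, 17 adjusted over the list alone (camera adjusted p = 2.53e-06; adjusted p = 0.346 with an estimated correlation), for example RPLP0 (1.13 ± 0.172) and RPS18 (1.35 ± 0.218, and 0.899 without PA 12 h replicate 1). RNAs of the mitochondrial genome were higher in 9 of 13 cases and in 11 adjusted over the list alone (camera adjusted p = 0.00214; adjusted p = 0.548 with an estimated correlation). They took 6.88% ± 1.23 of the reads with PA and 4.55% ± 0.0269 with DMSO. Without PA 12 h replicate 1, 2 of 13 were higher and the list was not called (adjusted p = 0.0713), MT-ND3 (1.83 ± 0.262) stood at 1.11 and MT-CO1 (0.82 ± 0.203) at 0.317 (adjusted p = 0.062).

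In total 7363 genes (48.5%) passed at 12 h, 3698 higher and 3665 lower, and 3208 changed at least 2-fold (1413 higher and 1795 lower). On the scale of log2(RPKM + 1), which carries no TMM factor, changes differed from those with TMM by a median per gene of -0.128 (median change -0.03, against 0.01 with TMM), and 41.6% of the called genes were higher. After correction for GC content and transcript length 6008 genes passed (2914 higher and 3094 lower). Among them, 3966 were among the 7363, and 3813 of them had the same direction. The PA 12 h replicates differed more from each other than those of any other group (Spearman correlation across genes 0.978). The p-values rest on a spread estimated over all 7 groups. With the 4 libraries of each comparison alone, 3618 genes passed at 12 h, 1182 at 3 h and 8492 at 24 h. How far the totals differ between times thus depends on that shared spread. The total was 4750 without DMSO 12 h replicate 1, 5271 without DMSO 12 h replicate 2, 4500 without PA 12 h replicate 1 and 8677 without PA 12 h replicate 2.

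At 24 h ALDOC rose by 4.31 ± 0.348 (adjusted p = 2.13e-06) and ACSS2 by 4.13 ± 0.248 (adjusted p = 7.12e-07). S100P, a calcium-binding protein gene (ENSG00000163993.6, chromosome 4, 6693069 to 6697170), rose by 4.39 ± 0.578, from 0.187 ± 0.0835 to 4.01 ± 0.836 CPM (adjusted p = 5.75e-05). The siderophore-binding gene LCN2 rose by 4.16 ± 0.394 (adjusted p = 5.81e-06), and ATF3, a stress transcription factor (ENSG00000162772.15, chromosome 1, 212565334 to 212620777), by 3.98 ± 0.217, from 3.59 ± 0.563 to 56.9 ± 8.98 CPM (adjusted p = 5.54e-07). LCN2 fell in DMSO between 0 and 24 h, from 4.24 ± 0.419 to 0.299 ± 0.0746 CPM, and was at 5.40 ± 0.503 CPM with PA at 24 h. The carbonic anhydrase gene CA9 rose by 4.27 ± 0.763 (adjusted p = 0.000465) to 4.27 ± 1.16 CPM. DMSO 24 h replicate 2 held 0 reads of it, so its fold depends on the other DMSO library. It was 3.3 without DMSO 24 h replicate 2 and 10.1 without DMSO 24 h replicate 1, a fitted value against 0 reads that is no bound. The microtubule genes TPPP3 (4.08 ± 0.429) and TUBB2B (4.05 ± 0.4, uncertain because near-identical tubulin copies share its reads) were also among the 8 largest rises. FAM111B (-4.21 ± 0.444), SGOL2 (-4.21 ± 0.461), CENPE (-4.16 ± 0.374), ASPM (-3.97 ± 0.527), the kinesins KIF15 (-4.02 ± 0.427) and KIF18A (-3.96 ± 0.457), EDRF1 (-3.97 ± 0.391) and the ubiquitin ligase gene TRIM59 (-3.71 ± 0.33) fell most. Without PA 24 h replicate 1, 7 of these 8 falls grew by over 1.5-fold: ASPM stood at -4.89, SGOL2 and CENPE at -4.86, FAM111B at -4.81, KIF18A at -4.79, EDRF1 at -4.71 and KIF15 at -4.70. ASPM stood at -3.38 without PA 24 h replicate 2. MKI67 (ENSG00000148773.11, chromosome 10, 128096659 to 128126385) fell by 2.40 ± 0.162, from 802 ± 58.8 to 152 ± 38.9 CPM (adjusted p = 1.19e-06). CDKN1A (ENSG00000124762.12, chromosome 6, 36676460 to 36687339) rose by 2.40 ± 0.182, from 19.4 ± 2.15 to 103 ± 18.4 CPM (adjusted p = 1.67e-06). HMOX1 rose by 2.45 ± 0.254 (adjusted p = 9.98e-06), CXCL8 by 1.26 ± 0.272 (adjusted p = 0.0016; 11.3 ± 0.953 CPM with PA, below the 37.7 ± 3.00 CPM of DMSO at 0 h) and GAPDH by 1.54 ± 0.157 (adjusted p = 9.26e-06). CDKN2A had 6 reads over all 14 libraries, at most 3 in any of them, and was not tested.

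Of 30 lists, 13 were called at 24 h, of which 2 held with an estimated correlation. The mitosis list fell in 18 of 18 members, 18 adjusted over the list alone, with a median of -1.74 (camera adjusted p = 3.41e-11; adjusted p = 0.048 with an estimated correlation), as in the spindle factor TPX2 (-1.64 ± 0.114), KIF20A (-1.79 ± 0.127) and the mitotic kinase AURKA (-1.75 ± 0.131). Hypoxia genes rose in 13 of 15 cases, 13 adjusted over the list alone (camera adjusted p = 2.6e-08; adjusted p = 0.048 with an estimated correlation), as in NDRG1 (2.59 ± 0.146), PGK1 (2.08 ± 0.149), BNIP3 (1.59 ± 0.136) and ALDOA (2.15 ± 0.196). The next calls were lost with an estimated correlation. DNA replication genes fell in 16 of 20 cases (camera adjusted p = 4.62e-08; adjusted p = 0.0631 with an estimated correlation), among them MCM10 (-2.34 ± 0.187), MCM4 (-1.50 ± 0.117), MCM6 (-1.44 ± 0.143) and MCM3 (-1.33 ± 0.127). DNA repair genes fell in 17 of 18 cases (camera adjusted p = 6.21e-09; adjusted p = 0.107 with an estimated correlation), with EXO1 at -2.33 ± 0.188 and FANCD2 at -1.76 ± 0.154. Sterol synthesis genes rose in 14 of 16 cases (camera adjusted p = 1.01e-07; adjusted p = 0.107 with an estimated correlation), as in MVD (3.04 ± 0.213), FDPS (2.56 ± 0.191), LSS (2.11 ± 0.171) and DHCR7 (2.38 ± 0.193). Fatty acid genes rose in 8 of 10 cases (camera adjusted p = 0.000455; adjusted p = 0.107 with an estimated correlation), with FADS2 at 2.78 ± 0.183, ACLY at 2.10 ± 0.143 and SCD at 2.76 ± 0.208. Counts adjusted over the list alone were the same for these 4 lists and for the stress lists that follow, except where given.

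Stress lists were called at 24 h as well. ATF4 stress genes rose in 11 of 13 cases (camera adjusted p = 4.48e-07; adjusted p = 0.107 with an estimated correlation), among them DDIT3 (2.49 ± 0.205), CHAC1, which degrades glutathione (2.49 ± 0.235), and DDIT4 (2.23 ± 0.177). NRF2 targets rose in 9 of 15 cases and fell in 1 (camera adjusted p = 0.00053; adjusted p = 0.0549 with an estimated correlation), with the thioredoxin reductase TXNRD1 at 1.16 ± 0.111 and TKT at 1.74 ± 0.203. Immediate early genes rose in 12 of 16 cases (camera adjusted p = 4.67e-05; adjusted p = 0.109 with an estimated correlation), such as KLF2 (2.99 ± 0.342), JUNB (1.44 ± 0.161) and KLF4 (0.97 ± 0.145). Their median was 0.95, and in DMSO it moved by -0.84 from 0 to 24 h. After correction for GC content and transcript length 8 rose and 1 fell. Epithelial genes rose in 7 of 13 cases and fell in 2 (camera adjusted p = 0.00999; adjusted p = 0.107 with an estimated correlation), with the keratins KRT19 (2.20 ± 0.188), KRT8 (1.78 ± 0.169) and KRT18 (1.40 ± 0.172), both with pseudogene copies, and the claudin CLDN7 (1.85 ± 0.211). In the autophagy and lysosome list 12 of 16 rose and 1 fell (camera adjusted p = 5.61e-05; adjusted p = 0.23 with an estimated correlation), among them MAP1LC3B (1.20 ± 0.135), ULK1 (1.64 ± 0.194), SQSTM1 (1.55 ± 0.167) and CTSD (1.81 ± 0.196). Ribosomal protein genes were higher in 19 of 20 cases and in 20 adjusted over the list alone (camera adjusted p = 4.62e-08; adjusted p = 0.215 with an estimated correlation), with RPS3 at 1.70 ± 0.217 and RPS14 at 1.41 ± 0.187. Their median was 0.96, and lists matched on GC content, transcript length and abundance had a median of 0.57 (middle 95% from 0.21 to 0.87), so matched genes also rose. Matched medians were 0.38 for ATF4 stress (list median 1.35), 0.29 for autophagy (0.79), 0.15 for NRF2 targets (0.76) and -0.57 for DNA repair (-1.68). RNAs of the mitochondrial genome were higher in 13 of 13 cases (camera adjusted p = 3.14e-06; adjusted p = 0.325 with an estimated correlation), with MT-ND3 at 2.31 ± 0.266 and MT-CO2 at 1.62 ± 0.204. They took 9.13% ± 1.27 of the reads with PA and 5.02% ± 0.372 with DMSO.

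**Figure D1:**
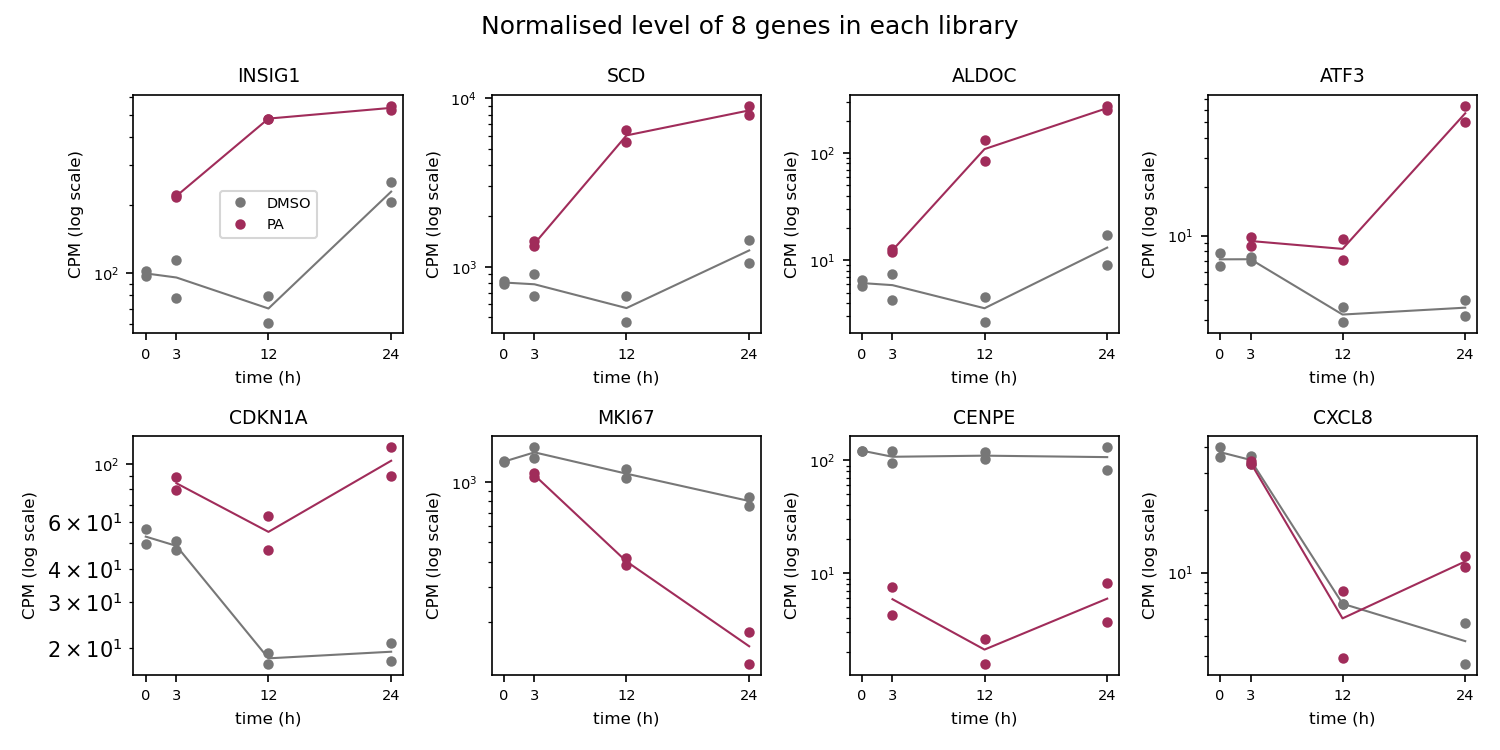
Abundance (CPM, log scale) of 8 genes by time in h for DMSO (grey) and PA (purple), with dots for the 2 libraries of each group and lines through the group means. CENPE was at 5.90 CPM with PA against 108 CPM with DMSO at 3 h, and SCD at 6026 CPM against 568 CPM at 12 h.

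In total 8296 genes (54.7%) passed at 24 h, 4127 higher and 4169 lower, and 4227 changed at least 2-fold (1946 higher and 2281 lower). On the log2(RPKM + 1) scale changes differed from those with TMM by a median per gene of -0.282 (median change -0.10, against -0.01 with TMM), and 32.6% of the called genes were higher, against 49.7% with TMM. The 10 most abundant genes took 13.1% ± 1.23 of the reads with PA and 8.72% ± 0.746 with DMSO. After correction for GC content and transcript length 7397 genes passed (3676 higher and 3721 lower), 5224 of them among the 8296 and 5081 in the same direction.

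**Figure D2:**
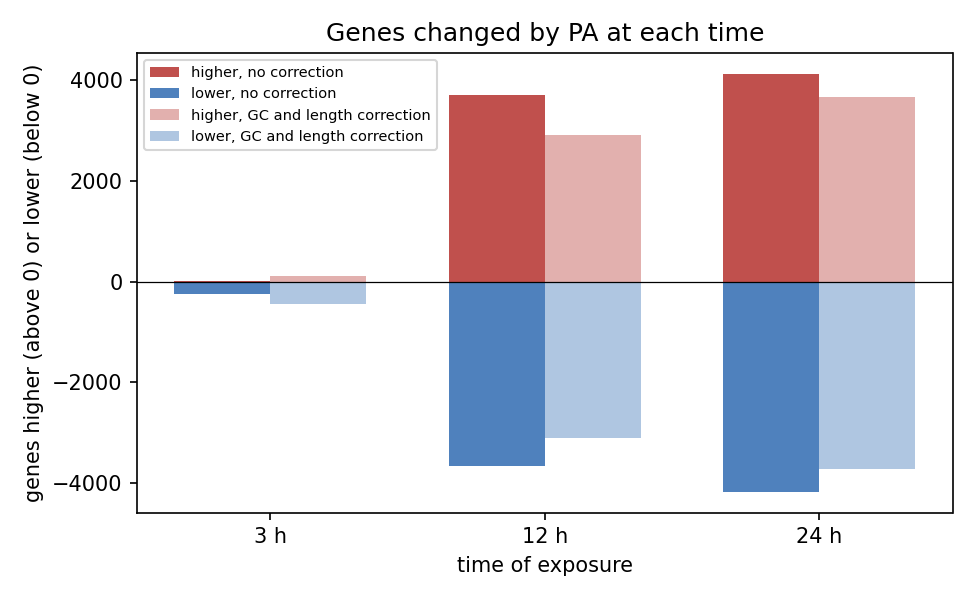
Number of genes higher and lower with PA than with DMSO at 3, 12 and 24 h (bars), without and with correction of each library for GC content and transcript length. Uncorrected calls were 21 higher and 240 lower at 3 h, and 4127 higher and 4169 lower at 24 h.

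Averaged over the 3 times, 6 PA libraries against 6 DMSO libraries, 9693 genes (63.9%) passed, 4785 higher and 4908 lower, of which 2528 changed at least 2-fold (902 higher and 1626 lower). On the log2(RPKM + 1) scale 9263 passed, 3707 higher and 5556 lower. ALDOC (3.44 ± 0.199), ACSS2 (2.97 ± 0.137), the glucocorticoid-induced gene TSC22D3 (2.44 ± 0.145), the sterol reductase TM7SF2 (2.43 ± 0.135), MVD (2.41 ± 0.121) and the uroplakin UPK1A (2.33 ± 0.178) rose most. CENPE (-4.68 ± 0.223), SGOL2 (-3.63 ± 0.258), KIF20B (-3.61 ± 0.26), FAM111B (-3.60 ± 0.249), ASPM (-3.51 ± 0.298) and ANKRD12 (-3.42 ± 0.176) fell most, with adjusted p = 2.45e-08 for CENPE and ANKRD12. The same 13 lists as at 24 h were called, and 0 with an estimated correlation. They included hypoxia with 15 of 15 members higher (camera adjusted p = 1.25e-07; adjusted p = 0.118 with an estimated correlation) and mitosis with 15 of 18 lower (camera adjusted p = 1.25e-07; adjusted p = 0.122 with an estimated correlation). The immediate early list (camera adjusted p = 0.0294; adjusted p = 0.375 with an estimated correlation) was not called after correction for GC content and transcript length (adjusted p = 0.71). Not called at first but called after it were iron genes as higher (adjusted p = 0.000968), and Wnt and Notch targets (adjusted p = 0.0371) and TGF-beta and YAP targets (adjusted p = 0.0421) as lower. That correction left 8579 genes, 6390 of them among the 9693 and 5764 in the same direction. Of the 240 genes lower at 3 h, 232 were lower at 12 h (57.9 would be shared if calls were independent) and 230 at 24 h (65.9). Of the 21 higher at 3 h, 15 were higher at 12 h (5.12) and 21 at 24 h (5.71). The 12 and 24 h calls shared 3055 higher genes (1005) and 3047 lower genes (1006). The numbers for independent calls take no account of the GC trend that the PA libraries share, which can add shared calls.

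**Figure D3:**
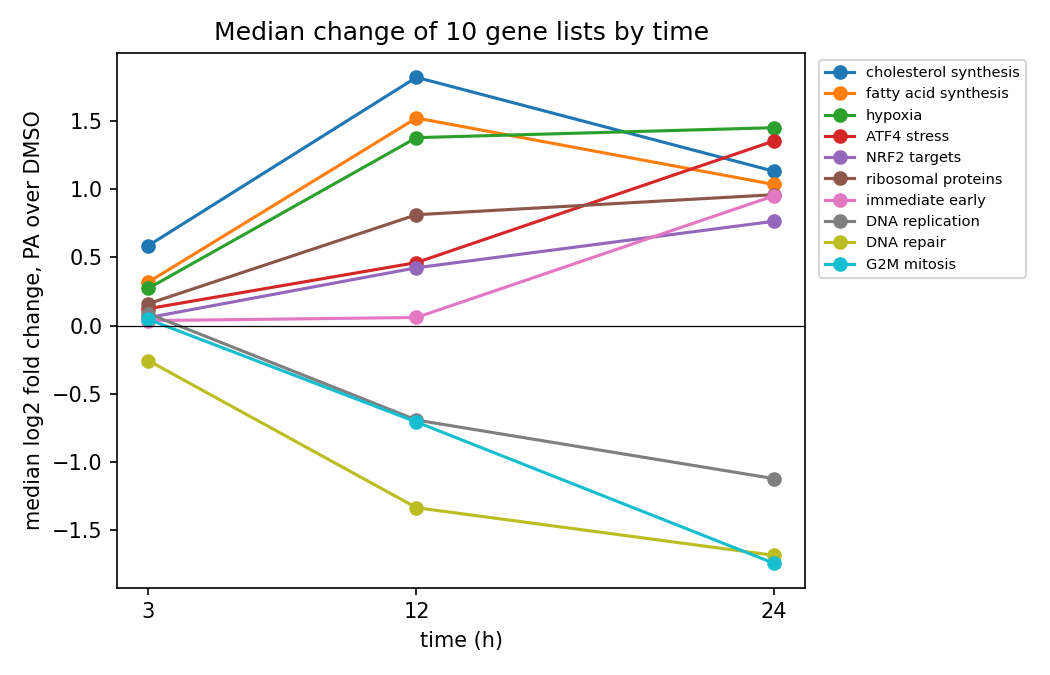
Median log2 change, PA over DMSO, of 10 gene lists (lines) at 3, 12 and 24 h. The sterol synthesis median was 0.59, 1.82 and 1.13, and the mitosis median 0.05, -0.71 and -1.74. In DMSO against 0 h the sterol synthesis median was -0.43 at 12 h and 0.45 at 24 h.

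Whether the PA effect itself changed with time was tested as an interaction. From 3 to 12 h the effect grew most for ALDOC (3.85 ± 0.475, adjusted p = 0.00181) and ACSS2 (3.20 ± 0.321, adjusted p = 0.000743), with 423 genes past the threshold (319 upward and 104 downward). Sterol synthesis moved upward in 10 of 16 members (camera adjusted p = 3.51e-16; adjusted p = 0.0293 with an estimated correlation), fatty acid synthesis in 5 of 10 and hypoxia in 6 of 15, and in 15, 6 and 11 adjusted over the list alone. Mitosis moved downward in 5 of 18 members (camera adjusted p = 5.1e-10; adjusted p = 0.0293 with an estimated correlation) and DNA replication in 3 of 20, and in 15 and 13 adjusted over the list alone. These 5 lists held with an estimated correlation, at the same adjusted p of 0.0293. From 3 to 24 h, 2192 genes differed (1251 upward and 941 downward), led by TPPP3 (3.71 ± 0.692), ATF3 (3.61 ± 0.287), LCN2 (3.51 ± 0.498) and, downward, EDRF1 (-3.25 ± 0.503), DEPDC1 (-2.64 ± 0.523) and the topoisomerase TOP2A (-2.62 ± 0.524). Mitosis genes moved downward in 15 of 18 cases (camera adjusted p = 1.68e-16; adjusted p = 0.0179 with an estimated correlation) and DNA replication genes in 16 of 20 (camera adjusted p = 1.07e-14; adjusted p = 0.0179 with an estimated correlation), 17 of each list adjusted over the list alone. Of 14 lists called for 3 to 24 h these 2, hypoxia and NRF2 targets held with an estimated correlation. From 12 to 24 h, 64 genes differed (40 upward and 24 downward): the growth factor HBEGF (3.71 ± 0.375, adjusted p = 0.00187), KLF2 (3.32 ± 0.505, adjusted p = 0.0137), ANKRD1 (2.74 ± 0.309, adjusted p = 0.0024) and ATF3 (2.64 ± 0.294, adjusted p = 0.0024) moved upward most. Immediate early genes moved upward in 4 of 16 cases (camera adjusted p = 3.26e-14; adjusted p = 0.0301 with an estimated correlation) and ATF4 stress genes in 5 of 13 (camera adjusted p = 4.08e-13; adjusted p = 0.0413 with an estimated correlation), 9 of each list adjusted over the list alone. The PA effect on sterol synthesis was smaller at 24 h than at 12 h, with a median difference of -0.49. In this list 1 member was past the threshold, 3 adjusted over the list alone (camera adjusted p = 2e-08; adjusted p = 0.0868 with an estimated correlation). Against 0 h the DMSO median of this list was -0.43 at 12 h and 0.45 at 24 h. The smaller effect thus went with a rise in DMSO and is not a shown fall in the PA libraries. Of 18 lists called for 12 to 24 h, 5 held with an estimated correlation: immediate early genes, ATF4 stress, mitosis (5 of 18 members lower, adjusted p = 0.0301), DNA replication (adjusted p = 0.0413) and NRF2 targets (adjusted p = 0.0424).

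The share of upward calls depended on the processing. With limma on log2(RPKM + 1), which changed the test as well as the scaling, 24.8% of the 3 to 24 h calls were upward (57.1% in edgeR with TMM). For 12 to 24 h the share was 36.5% (62.5% in edgeR with TMM). Median differences per gene were -0.305 and -0.145. With only the size factors changed to those of DESeq2, the shares were 58% and 67.2%. Those factors and TMM both assume that most genes do not change. Their likeness therefore cannot show whether the share depends on the scaling. For 3 to 12 h the share was 57.9% with limma on log2(RPKM + 1), 59.9% in DESeq2 and 75.4% in edgeR with TMM. It was 71.7% in edgeR with DESeq2-type size factors. The median difference per gene between log2(RPKM + 1) and TMM was -0.151. After correction for GC content and transcript length 1036, 2862 and 331 genes passed, with 370, 1679 and 63 of the uncorrected calls among them. The 423 calls from 3 to 12 h became 5007 without PA 12 h replicate 2, 92 without DMSO 3 h replicate 1, 176 and 61 without PA 3 h replicate 1 and 2, 85 and 42 without DMSO 12 h replicate 1 and 2, and 277 without PA 12 h replicate 1. Those from 3 to 24 h became 739 without DMSO 3 h replicate 1, 1266 and 705 without PA 3 h replicate 1 and 2, 817 and 684 without DMSO 24 h replicate 1 and 2, and 1092 without PA 24 h replicate 2. The 64 calls from 12 to 24 h became 8 and 4 without DMSO 12 h replicate 1 and 2, 521 and 323 without PA 12 h replicate 1 and 2, 3 and 14 without DMSO 24 h replicate 1 and 2, and 22 without PA 24 h replicate 1.

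Change over time in the DMSO cultures is the background of these comparisons; the 3 contrasts share the 0 h libraries. Some inflammatory genes were lower at 12 and 24 h than at 0 h. CXCL8, a neutrophil chemokine (ENSG00000169429.9, chromosome 4, 73740506 to 73743716), was at 37.7 ± 3.00 CPM at 0 h, fell by 2.41 ± 0.268 by 12 h (5.30-fold lower, adjusted p = 0.00111) and was 7.99-fold lower at 24 h (adjusted p = 0.000112). LCN2 (-2.93 ± 0.363 and -3.82 ± 0.397), the chemokine CX3CL1 (-2.39 ± 0.24 and -2.72 ± 0.244) and the xenobiotic enzyme CYP1A1 (-2.40 ± 0.28 and -2.52 ± 0.283) were also lower at 12 and 24 h. LCN2 at 12 h (-2.42, adjusted p = 0.0597) did not pass without DMSO 12 h replicate 2 and stood at -3.65 without DMSO 12 h replicate 1, and CYP1A1 at 12 h did not pass without DMSO 12 h replicate 1 (adjusted p = 0.0521). At 12 h ARHGAP22 (1.48 ± 0.219), CMTM8 (1.19 ± 0.197), ZNF100 (1.19 ± 0.269) and the interleukin receptor IL6R (1.09 ± 0.175) rose most, and each lost its call without DMSO 0 h replicate 2, DMSO 12 h replicate 1 or DMSO 12 h replicate 2, and all but CMTM8 also without DMSO 0 h replicate 1, for example ZNF100 at 0.89 (adjusted p = 0.502) without DMSO 0 h replicate 2. At 24 h PCDH18 (1.79 ± 0.345), the cyclin CCNG2 (1.65 ± 0.2), RHOV (1.58 ± 0.222) and the clock output gene DBP (1.48 ± 0.219) rose most. PCDH18 lost its call in each of the 4 leave-outs (adjusted p from 0.0647 without DMSO 24 h replicate 2 to 0.184 without DMSO 24 h replicate 1), RHOV without DMSO 24 h replicate 1 (adjusted p = 0.0614), and DBP without DMSO 24 h replicate 1 (adjusted p = 0.0651) or DMSO 0 h replicate 2 (adjusted p = 0.0503).

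The NF-kB list had 9 of 17 members lower at 12 h and 11 adjusted over the list alone (camera adjusted p = 5.27e-15; adjusted p = 0.00139 with an estimated correlation). At 24 h 11 were lower, and 16 adjusted over the list alone (camera adjusted p = 1.98e-20; adjusted p = 0.000503 with an estimated correlation). At 24 h immediate early genes fell in 7 of 16 cases and in 12 adjusted over the list alone (camera adjusted p = 3.55e-12; adjusted p = 0.0324 with an estimated correlation). TGF-beta and YAP targets fell in 7 of 16 and in 8 adjusted over the list alone (camera adjusted p = 1.86e-08; adjusted p = 0.0184 with an estimated correlation). Aryl hydrocarbon receptor targets fell in 2 of 6 and in 3 adjusted over the list alone (camera adjusted p = 0.000511; adjusted p = 0.0418 with an estimated correlation). These were the calls that held with an estimated correlation, 1 of 14 at 12 h and 4 of 12 at 24 h. Among PA calls in the opposite direction, NRF2 targets moved in DMSO by a median of -0.25 at 12 h and -0.31 at 24 h, and RNAs of the mitochondrial genome by -0.40 and -0.41. Ribosomal protein genes moved in DMSO by -0.42 at 12 h. Sterol synthesis was called lower in DMSO at 12 h (median -0.43, 3 of 16 members, 7 adjusted over the list alone; camera adjusted p = 2.32e-06; adjusted p = 0.208 with an estimated correlation) and higher at 24 h (median 0.45, 1 member, 5 adjusted over the list alone; camera adjusted p = 5.08e-05; adjusted p = 0.241 with an estimated correlation). At 3 h camera called 3 lists, among them RNAs of the mitochondrial genome (lower, camera adjusted p = 1.89e-14), with 0 members past the threshold and 0 lists called with an estimated correlation. In total 221 genes passed at 12 h (49 higher and 172 lower) and 373 at 24 h (80 higher and 293 lower). On log2(RPKM + 1) the higher share was 38.4% at 12 h (22.2% with TMM) and 35.5% at 24 h (21.4% with TMM). At 3 h edgeR called 0 genes, with 215 at an unadjusted p under 0.05, and DESeq2 also called 0. After correction for GC content and transcript length 842 genes passed at 12 h and 1322 at 24 h, with 213 and 367 of the uncorrected calls among them. The 12 h total was 57 and 13 without DMSO 0 h replicate 1 and 2, and 9 and 12 without DMSO 12 h replicate 1 and 2. The 24 h total was 91 and 71 without DMSO 0 h replicate 1 and 2, and 26 and 105 without DMSO 24 h replicate 1 and 2.

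Abundance depended on GC content differently in the PA and the DMSO libraries. Slopes were taken on log2 CPM less each gene's mean over the 14 libraries. Their signs are therefore relative, and only differences between libraries carry meaning. The slope per 10 percentage points was -0.168 ± 0.0821 at 0 h, -0.140 ± 0.110 at 3 h, -0.306 ± 0.0184 at 12 h and -0.242 ± 0.0348 at 24 h in DMSO libraries. It was 0.0955 ± 0.0955 at 3 h, 0.351 ± 0.321 at 12 h and 0.409 ± 0.115 at 24 h in PA libraries, and the PA 12 h replicates stood at 0.578 and 0.124.

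**Figure D4:**
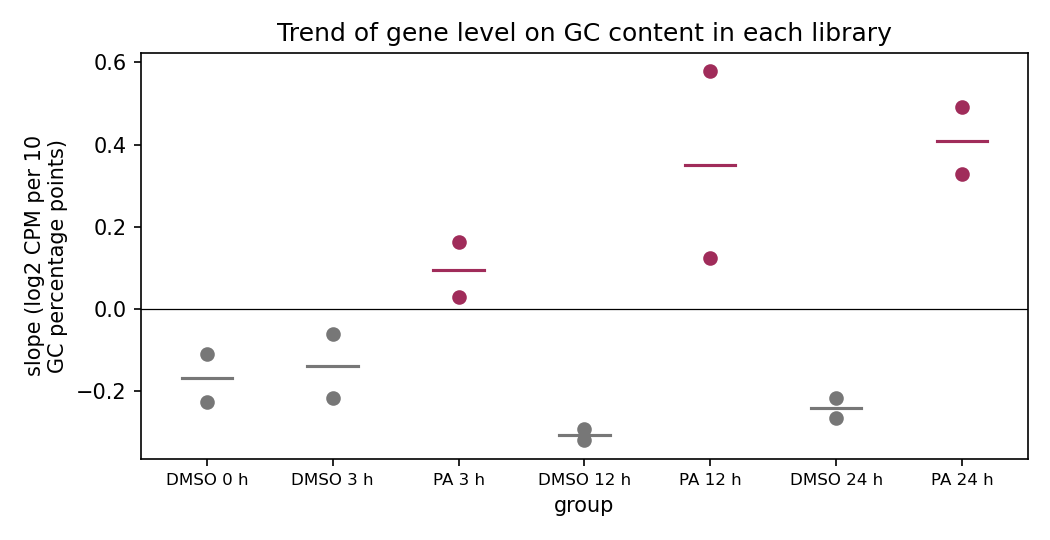
Slope of log2 CPM, less each gene's mean over libraries, on GC content (log2 units per 10 percentage points) by time in h. Dots show the 2 libraries of each group and lines the group means. Signs are relative to the mean over libraries. The 6 PA libraries lay between 0.028 and 0.578, above the 8 DMSO libraries, which lay between -0.319 and -0.062.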

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

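The corrections for GC content and transcript length in this part, the use of the longest transcript for both, the test by removal of the GC trend alone, the comparison of the 3 h slopes with the width of the DMSO range and the setting aside of the slope criterion for carry-over were chosen after the data had been seen.

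The tests of whether the PA effect differed between times brought up the following results. Between 3 and 12 h 423 genes differed. ALDOC (3.85), ACSS2 (3.20), TJP3 (3.01) and UPK1A (2.86) moved upward most on the log2 scale, and ZNF92 (-2.88), FAM111B (-2.46), CEP135 (-2.22) and KIF14 (-2.17) downward. Between 3 and 24 h 2192 genes differed, with TPPP3 (3.71), ATF3 (3.61), LCN2 (3.51) and ACSS2 (3.34) upward and EDRF1 (-3.25), DEPDC1 (-2.64), TOP2A (-2.62) and DLGAP5 (-2.60) downward. Between 12 and 24 h 64 genes differed, with HBEGF (3.71), KLF2 (3.32), ANKRD1 (2.74) and ATF3 (2.64) upward and ZNF792 (-2.42), PIF1 (-2.06), SOX21 (-2.00) and AXIN2 (-1.85) downward. ALDOC, ACSS2, TPPP3, ATF3, LCN2, EDRF1, DEPDC1, TOP2A, HBEGF and ANKRD1 kept their calls without any 1 library. EDRF1 stood at -3.99 without PA 24 h replicate 1.

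The other genes lost their calls without some libraries. From 3 to 12 h, TJP3 did so without DMSO 3 h replicate 1 or 2, PA 3 h replicate 2 or DMSO 12 h replicate 2 (adjusted p up to 0.14). UPK1A did so without DMSO 3 h replicate 1 (adjusted p = 0.0653) or DMSO 12 h replicate 2 (adjusted p = 0.0547). FAM111B (adjusted p up to 0.214) and CEP135 (up to 0.173) kept theirs only without PA 3 h replicate 1 or PA 12 h replicate 2. ZNF92 (up to 0.221) and KIF14 (up to 0.192) kept theirs only without PA 12 h replicate 2. Without PA 12 h replicate 2, ZNF92 stood at -5.00, FAM111B at -3.44 and KIF14 at -2.76. Without PA 12 h replicate 1, ZNF92 stood at -2.06 and TJP3 at 2.35. Without PA 3 h replicate 2, ZNF92 stood at -2.29 and FAM111B at -1.77. TJP3 stood at 3.93 and 2.41 without DMSO 12 h replicate 1 and 2. From 3 to 24 h, DLGAP5 lost its call without DMSO 3 h replicate 1 (adjusted p = 0.057) or PA 24 h replicate 2 (adjusted p = 0.0527). From 12 to 24 h, KLF2 lost its call without DMSO 12 h replicate 1 or 2 or DMSO 24 h replicate 1 (adjusted p up to 0.12), and stood at 3.97 without PA 12 h replicate 1. ZNF792 (adjusted p up to 0.22), PIF1 (up to 0.133) and AXIN2 (up to 0.27) lost theirs without any 1 of the DMSO 12 h, DMSO 24 h and PA 24 h libraries. SOX21 (up to 0.146) lost its call without any of these but PA 24 h replicate 2.

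The 240 genes lower with PA at 3 h were poor in GC content (median 40.01% against 48.9% over tested genes) and long. A smooth trend of the libraries on GC content, alone or with transcript length, is argued against as the whole cause, since 227 of the 237 genes with a value stayed lower after its removal and their median moved from -1.54 to -1.28. The slopes themselves do not exclude a trend of the size seen between DMSO libraries. Of the PA slopes 6 of 6 lay outside the DMSO range, which met the criterion set beforehand against such a trend. By the condition added later they do not decide, since the difference at 3 h (0.235, pairings 0.09 to 0.380) was below the width of that range (0.257). Carry-over of the compound into the RNA stays open. The slope difference was 2.77 times as large at 24 h (pairings 0.545 to 0.757) as at 3 h, which met the criterion set beforehand against it, but that criterion was wrong: the slope does not measure this pattern, since 227 genes stayed lower once the trend was removed. A loss of particular RNAs in PA samples before sequencing, through sequence features other than GC content and length, was not tested and stays open beside a cellular response to PA.

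Mitosis genes were lower with PA at 24 h, with a median of -1.74. None of 10000 lists matched on GC content, length and abundance lay as low (percentile 0, matched median -0.148, middle 95% from -0.551 to 0.245), and 18 of 18 members stayed lower after the correction. Bias by GC content and transcript length is thus excluded as the whole cause. A cellular response to PA and technical causes outside these properties stay open, since PA exposure and the library trends go together in this design.

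Sterol synthesis genes were higher with PA at 12 h, with a median of 1.82. It lay above all 10000 matched lists (percentile 100, matched median -0.024, middle 95% from -0.435 to 0.349), and 15 of 16 members were higher after the correction. Bias by GC content and transcript length is excluded as the whole cause for this list as well. The DMSO libraries alone moved by a median of -0.43 from 0 to 12 h, which is less than the difference between PA and DMSO. A cellular response to PA remains a hypothesis found and examined on the same libraries, and other technical causes that go with PA stay open.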

How the results depend on the processing

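The alternatives with a GC or GC and length correction, those on both transcript definitions, the block joined to the correction, and the removal of mitochondrial genes were chosen after the data had been seen. The cause of each change was not tested unless it is given.

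Among 224 named gene results, 198 passed, 169 kept direction and side of the threshold under every alternative and leave-out, and 2 reversed in any. CEBPB at 12 h became -0.103 with the GC correction, -0.147 with the GC and length correction, -0.146 with the block added to it and -0.131 on transcript medians. CXCL8 at 12 h, not called at first, became 0.951, 0.845, 0.847 and 0.675 in that order. DESeq2 brought 13 named results past the threshold and ended 0, no filter brought 15 and ended 0, and the block ended 7.

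Totals for PA against DMSO at 3 h (261) became 582 with DESeq2, 1115 without a filter, 1182 with the 4 libraries alone, 118 with log2(RPKM + 0.1), 541 with the GC correction, 565 with GC and length, 476 with the block and GC and length, and 558 on transcript medians. At 12 h (7363) the total was 3618 with the 4 libraries alone. A minimum of 2-fold, which can only lower a count, left 3208 at 12 h, 4227 at 24 h, 2528 for the average, 1337 for 3 to 24 h, 89 for DMSO at 12 h and 123 for DMSO at 24 h.

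For the change in effect from 3 to 12 h (423) the totals were 1208 with DESeq2, 1808 without a filter, 250 with log2(RPKM + 0.1), 1097 with the GC correction, 1036 with GC and length, 913 with the block and GC and length, and 1001 on transcript medians. From 12 to 24 h (64) they were 203 with DESeq2, 269 without a filter, 23 with the block, 294, 331 and 261 with the GC correction, with GC and length and with the block joined to it, and 330 on transcript medians.

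DMSO at 3 h (0 genes in edgeR, 215 at an unadjusted p under 0.05, 0 in DESeq2) gave 11 genes without a filter and 1 with log2(RPKM + 0.1). DMSO at 12 h (221) gave 688 with DESeq2, 849 without a filter, 113 with the block, 2864 with the 4 libraries alone, 142 with log2(RPKM + 0.1), 1102 with the GC correction, 842 with GC and length, 668 with the block and GC and length, and 859 on transcript medians. DMSO at 24 h (373) gave 759 with DESeq2, 703 without a filter, 2570 with the 4 libraries alone, 1332, 1322 and 1200 with the GC correction, with GC and length and with the block joined to it, and 1337 on transcript medians.

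Leaving out 1 library at a time gave 29 to 178 genes at 3 h, 4500 to 8677 at 12 h, 6139 to 7538 at 24 h and 8863 to 10379 for the average. The differences gave 42 to 5007 (3 to 12 h), 684 to 1855 (3 to 24 h) and 3 to 521 (12 to 24 h). DMSO gave 0 at 3 h, 9 to 57 at 12 h and 26 to 105 at 24 h. A group left with 1 library was assumed to vary like the other groups, and fewer libraries leave fewer degrees of freedom.

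The block for the replicate number, without pairing shown by the data, gave 221 genes at 3 h, 7098 at 12 h, 8033 at 24 h, 285 for 3 to 12 h and 259 for DMSO at 24 h. With it 6, 12, 13 and 13 lists were called at 3 h, 12 h, 24 h and on average, against 6, 11, 13 and 13 without. With an estimated correlation between genes 0, 0, 2 and 0 lists were called. Without mitochondrial genes the totals were 261, 7348, 8265 and 9674 for 3 h, 12 h, 24 h and the average.

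Depth limits genes near the floor of 0.0852 to 0.114 CPM. CDKN2A had 6 reads in all, found only in replicate 2 of PA at 3 h (2 reads), 12 h (3) and 24 h (1). It thus stood at no more than 0.108 CPM in any library, within the range of that floor. The reason for its near absence was not tested.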

Other observations

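The test of genomic span and the corrections for GC content and transcript length in this part were chosen after the data had been seen, and so were the list members named here.

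At 24 h, 17 lists were not called by camera without the correction, and most held members that rose with PA and members that fell. Each named member passed at an adjusted p under the threshold, and kept its call and direction after correction for GC content and transcript length and on the log2(RPKM + 1) scale and without any 1 of the 4 libraries, except where stated. Counts adjusted over the list alone differ only where they are given. Among iron genes 4 of 8 rose and 3 fell (camera adjusted p = 0.361). The ferritin genes FTH1 (1.98 ± 0.201) and FTL (1.64 ± 0.2), which have pseudogene copies, rose. The transferrin receptor TFRC fell by 0.52 ± 0.171. It stood at 0.16 (adjusted p = 0.193) after the correction and did not pass without DMSO 24 h replicate 1 or PA 24 h replicate 1 or 2 (-0.40, -0.53 and -0.48; adjusted p from 0.0723 to 0.148). The corrected list had 5 higher and 0 lower (camera adjusted p = 0.00221). This and the other corrected list p-values here rest on the preset correlation only. At 12 h it was also called after the correction and not without it (adjusted p = 0.000788, against 0.499). Of Wnt and Notch targets 1 of 12 rose and 6 fell (camera adjusted p = 0.158), with the Wnt feedback gene AXIN2 (-2.46 ± 0.261), the Notch ligand JAG1 (-1.37 ± 0.151) and HES1 (-0.83 ± 0.142) lower and HEY1 (1.46 ± 0.278) higher. After the correction 1 rose and 8 fell (adjusted p = 0.00546). p53 targets split, 8 of 15 up and 3 down (camera adjusted p = 0.112), or 8 up and 2 down after the correction (adjusted p = 0.0423). CDKN1A and the apoptosis inducer BBC3 (2.21 ± 0.215) rose, while the p53 ligase MDM2 (-1.32 ± 0.219) and the death receptor FAS (-2.55 ± 0.512) fell. NF-kB genes rose in 9 of 17 cases and fell in 2 (camera adjusted p = 0.152), or 7 and 1 after the correction (adjusted p = 0.0826), with the adhesion gene ICAM1 at 1.29 ± 0.137. Interferon genes rose in 5 of 13 and fell in 3 (camera adjusted p = 0.238), or 7 and 1 after the correction (adjusted p = 0.068), with ISG15 (1.64 ± 0.221) and ISG20 (2.16 ± 0.215) higher and the RNA sensor IFIH1 (-1.66 ± 0.312) lower.

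The small heat shock gene HSPB1 rose by 1.39 ± 0.175 and HSP90AA1 fell by 1.84 ± 0.305, in a list with 2 of 11 up and 4 down (camera adjusted p = 0.753). After the correction 1 was up and 7 were down (adjusted p = 0.074). In the endoplasmic reticulum list 6 of 13 rose and 3 fell (camera adjusted p = 0.456), or 4 and 3 after the correction, HERPUD1 rising by 1.32 ± 0.215 and HSP90B1 falling (-1.32 ± 0.217). Mesenchymal genes rose in 6 of 13 cases and fell in 3 (camera adjusted p = 0.361), or 5 and 3 after the correction. S100A4 (2.56 ± 0.225) and SPARC (1.99 ± 0.353) were higher, the cadherin CDH2 (-0.81 ± 0.155) and ZEB1 (-1.44 ± 0.316) lower. Extracellular matrix genes rose in 10 of 21 and fell in 4, or 5 adjusted over the list alone (camera adjusted p = 0.361), but 7 rose and 7 fell after the correction (adjusted p = 0.846), with TIMP1 at 1.38 ± 0.247 and the laminin LAMA3 at -1.04 ± 0.222. TGF-beta and YAP targets were 6 up and 6 down of 16 (camera adjusted p = 0.905), or 2 up and 6 down after the correction (adjusted p = 0.228), with THBS1 at -1.77 ± 0.223. At 12 h 6 rose and 8 fell (camera adjusted p = 0.251), and after the correction 0 rose and 9 fell (adjusted p = 0.0123). Apoptosis regulators were 5 up and 4 down of 16 (camera adjusted p = 0.587), or 7 up and 1 down after the correction (adjusted p = 0.109), with MCL1 at 0.68 ± 0.117 and the survivin gene BIRC5 at -1.06 ± 0.13. Clock genes were 6 up and 5 down of 15 (camera adjusted p = 0.616), or 4 up and 4 down after the correction, with DBP at 1.52 ± 0.198. Aryl hydrocarbon receptor targets were 1 up and 3 down of 6, or 2 up and 3 down adjusted over the list alone (camera adjusted p = 0.709). CYP1B1 stood at -1.16 ± 0.291, and at -0.91 (adjusted p = 0.067) without PA 24 h replicate 2. Metallothioneins, whose copies share reads, were 2 up and 1 down of 6, or 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.98), and 1 up and 2 down after the correction. Replication histones were 5 up and 0 down of 11, or 4 up adjusted over the list alone (camera adjusted p = 0.156), and 4 up and 2 down after the correction. Nuclear RNAs were 3 up and 2 down of 8 (camera adjusted p = 0.895), or 1 up and 2 down after the correction, with SNHG1 at -1.07 ± 0.162.

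Markers of other cell types were sparse. Of 3 measured leukocyte markers 2 rose at 24 h (camera adjusted p = 0.156), CD14 (1.57 ± 0.387) and CD68 (1.17 ± 0.206). Of 2 measured fibroblast markers COL1A1 rose by 0.65 ± 0.157 but stood at 0.09 (adjusted p = 0.643) after the correction and at 0.22 (adjusted p = 0.143) on the log2(RPKM + 1) scale, and COL3A1 did not pass (-0.32, adjusted p = 0.799). The 2 measured endothelial markers, KDR (-0.56, adjusted p = 0.378) and ESAM (0.27, adjusted p = 0.487), did not pass.

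A hypothesis that PA at 3 h lowered the RNA of genes with a long genomic span was tested against genes matched on GC content, transcript length and abundance. The median span of the genes lower at 3 h, 57.1 kb, was 1.1 times the matched median of 51.9 kb (percentile 86.0), under the bound of 1.5 times. No span difference of that size was thus seen beyond what goes with GC content, transcript length and abundance. The test cannot decide about span itself, since the matched genes share these properties and span was not compared without matching.

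For the average effect of PA, the libraries were regrouped within each time. Of 108 distinct splits 80 were drawn, the real one included. The real split gave 9693 genes. The highest other split gave 8726 and was counted with the true groups at 2 of the 3 times. Further splits counted in this way gave from 0 to 8279 genes. At the remaining time such a split either mixed PA and DMSO libraries or swapped the labels of both whole groups. A swap keeps the libraries of each group together. These kinds of split were not counted apart. The real split gave the most of the 80 drawn. A split that mixes PA and DMSO libraries at a time adds their difference to the spread between replicates, which lowers its count. The rank therefore shows that libraries of the same group resembled each other, and it does not decide about chance as a cause. Not all 108 splits were run. Regrouping libraries cannot exclude chance differences between cultures or preparations.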
